A study of Mus musculus with 6 samples.

How the data were processed

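Poly(A) RNA from bone marrow hematopoietic stem cells was extracted with Trizol and made into libraries with the VAHTS mRNA-seq v2 kit, per the labels' protocols. Whether the libraries keep strand is not given in the sources used here. HISAT2, StringTie and the builds mm8 and mm10 are named in the submitters' processing notes, without versions or roles. The files list 52550 genes with versioned Ensembl identifiers and coordinates. All 49035 identifiers found with the same version in GENCODE M21 had the same start and end there, so coordinates are given as GRCm38 (mm10). How reads were counted, and how reads mapping to several genes were treated, is not given in the sources used here.

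The deposited values are a signal per gene, one column per library, and the file headers call them only expression. Every value was a whole multiple of one step per library within 0.01 of a read (100% of values), with steps between 0.863 and 1.17. The values are thus gene-level read counts divided by one size factor per library, neither scaled to one common total nor divided by gene length, and they are called normalised read counts here. Division by the step recovered whole reads, and the totals were 37951985, 48665968 and 47815466 reads in WT replicates 1 to 3 and 46033994, 50992981 and 58692037 reads in KO replicates 1 to 3. Of all genes, 26485 were at 0 in every library. All 37 mitochondrially encoded genes were listed at 0 in all libraries and were therefore not analysed. The files give PCR reads without molecular identifiers, so floors of 3 reads per library cover counting error only.

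The comparison was KO against WT, 3 libraries each, grouped by the labels. The plan made before the data were examined foresaw counts or FPKM and TPM values. The values are of another kind, and the planned test for normalised values was used: limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend) on log2(value + 1), for genes with a value of at least 1 in at least 3 of the 6 libraries. The filter left 20136 genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. Count tests on the recovered reads, edgeR 4.0.16 (quasi-likelihood, filterByExpr, TMM) and DESeq2 1.42.0, were added as alternatives after seeing the data. A fold against a group at 0 in all libraries was computed against the floor of 3 reads in each library.

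Gene lists (35) and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry. This gave 33 tested lists, without the mitochondrially encoded genes and the sex-linked genes, which served as a check of the libraries. Of the listed symbols, 7 were matched through an older name. Some genes stand in more than 1 list. Named were Ppp2ca, and the 12 largest rises and 12 largest falls among called genes with non-overlapping groups, a mean of at least 5 CPM of recovered reads in the higher group and an informative symbol. Also named were up to 4 members with the smallest p of each list and 13 genes whatever their p: Hlf, Mecom, Procr, Kit, Ly6a, Cd34, Slamf1, Flt3, Trp53, Cdkn1a, Myc, Ctnnb1 and Ppp2cb. Genes named outside this rule are said to be so. Some genes the rule takes are not reported here.

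No pair of libraries agreed within sampling noise: the chi-square per degree of freedom over genes ranged from 45.8 to 258.7, so each library counted once. The procedure was tested on simulated data, with counts drawn for the real genes from the real means and library sizes and 200 genes changed. Over 10 simulations of KO against WT with a median of 20574 genes in the fit, it recovered 5.97% of genes changed 1.5-fold, 35.8% of those changed 2-fold and 63.2% of those changed 4-fold. Of 787 genes called, 80 were false, or 10.2%, above the nominal 5%. The real comparison called 4691 genes, far more than were changed in a simulation. With few changed genes the adjusted threshold is stricter, so the recovered shares do not describe the real comparison. That does not explain the false share, which was 8.79% among genes with a mean of at least 50. The real calls may thus also hold more false ones than the nominal 5%. Camera called a list of 48 further genes, all lowered by one common factor, in 10 of 10 simulations and an unchanged list in 0. Genes were drawn independently of each other, so this could not test the preset correlation.

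The alternatives planned were limma without the intensity trend, robust eBayes, library quality weights, upper quartile scaling, quantile normalization, a pseudocount of 0.1, no filter or a minimum of 5, a threshold of 2-fold, the replicate number as a block, leaving out each library, and camera with an estimated correlation and fry for lists. Added after seeing the data were edgeR, DESeq2, TMM scaling and a minimum of 10. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.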

Results

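Messenger RNA was sequenced from hematopoietic stem cells of mouse bone marrow, as the labels name the cells, in 3 wild-type and 3 knockout libraries. The wild-type (WT) mice carried floxed alleles of Ppp2ca, the gene of the main catalytic subunit of protein phosphatase 2A (PP2A), and no Cre recombinase is named for them. The knockout (KO) mice carried the same alleles with Vav1-Cre, a recombinase driver active in blood cells. The labels do not list the surface markers used to isolate the cells. In WT, the granulocyte-monocyte progenitor genes Ctsg and Ms4a3 averaged 106850 and 33779 normalised reads, and Mpo held 2.0% to 2.23% of all reads. The stem cell genes Hlf, Ly6a, Procr and Slamf1 averaged 1263.5, 613, 559 and 558, while Kit and Cd34 averaged 25717 and 42732. Levels of different genes do not give shares of cells, so the share of stem cells in these libraries was not determined. The libraries held between 37951985 and 58692037 reads over genes, recovered from the deposited values, with 20051 to 21362 genes above 0 in each. Nothing states that the libraries came from separate animals, so the p-values measure the spread between these 6 samples. The comparison addressed which genes differed in expression between KO and WT libraries. Bulk values cannot separate a change within cells from a different mix of cells, so a difference does not show regulation by Ppp2ca.

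The libraries separated by genotype. Pearson correlations across genes ranged from 0.956 to 0.965 within groups and from 0.916 to 0.943 between groups. The first principal component held 46.5% of the variance and put all 3 WT libraries on one side and all 3 KO libraries on the other. Xist was read in all 6 libraries, and the Y-linked genes Ddx3y, Eif2s3y and Uty had 0 reads in each, while Kdm5d had 1 read in KO replicate 2 and 0 in the others.

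**Figure D1:**
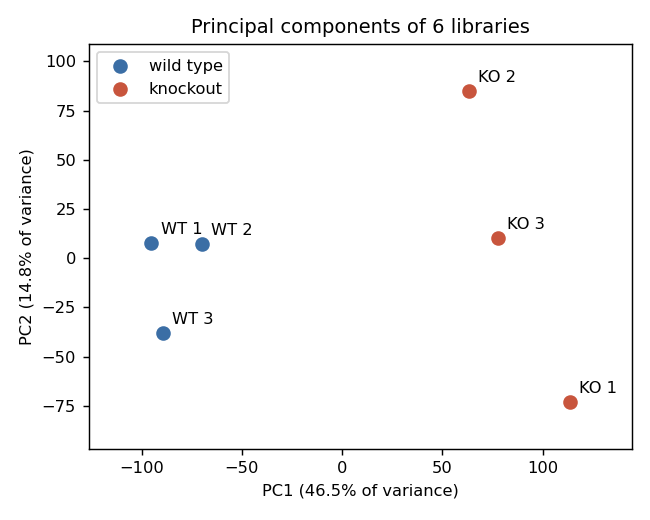
Principal components of the log2 values of the 20136 tested genes, with PC1 on the x axis, PC2 on the y axis and one point per library (WT blue, KO red). PC1 (46.5% of variance) separates the 3 WT from the 3 KO libraries, and PC2 (14.8%) spreads the KO libraries.

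The targeted gene was lower in every KO library but far from 0. Ppp2ca (ENSMUSG00000020349.4, GRCm38 chromosome 11, 52098681 to 52127778) had normalised read counts of 32909, 33451 and 33169 in WT and of 23728, 22419 and 24046 in KO. The means were 33176 ± 270.9 and 23398 ± 862.5 (SD, n = 3 each), so KO libraries kept 70.5% of the WT level. The log2 fold change was −0.50 ± 0.07 (SE), with an adjusted p of 0.00268 in limma. The values cover the whole gene and the deleted exons are not stated, so they do not measure the deletion itself. Ppp2cb, the paralogous catalytic subunit, averaged 603 ± 85.7 in WT and 1096 ± 463 in KO (log2 fold change 0.78, adjusted p = 0.102), a difference that did not pass the test. It passed in 4 of 19 alternatives, among them library quality weights, DESeq2 and the fit without KO replicate 2. Of 28 tested PP2A subunits and regulators, 3 rose and 2 fell, as also when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.209). Set, an inhibitor of PP2A, rose (log2 fold change 0.49), and so did the regulatory subunit Strn (0.54), whose call was lost without KO replicate 3 and without the intensity trend. C330027C09Rik, the gene of the PP2A inhibitor CIP2A, also rose (0.38), and its call was lost in 7 of 19 alternatives, with an adjusted p of up to 0.116.

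Expression differed widely between the genotypes. Of 20136 genes tested, 2069 were higher and 2622 lower in KO (limma, Benjamini-Hochberg adjusted p below 0.05), or 23.3% of those tested. Larger changes were mostly decreases: 493 genes rose and 1671 fell at least 2-fold. In 4689 of the 4691 called genes the 3 KO values lay outside the range of the 3 WT values, which a call on these same values nearly requires. Among all tested genes that share was 40.9%, where chance gives 10%. Both counts fell whichever library was left out, with fewer samples in each fit. Without KO replicate 3, 978 genes were higher and 1639 lower. Without WT replicates 1, 2 and 3, 1617, 1774 and 1723 genes were lower. Without the intensity trend 1071 genes were higher, and with library quality weights 3198. The excess of lower genes depended on scaling and on the genes counted. With upper quartile scaling 2464 genes were higher and 2472 lower. Among called genes with non-overlapping groups, at least 5 CPM in the higher group and an informative symbol, 1740 rose and 1658 fell.

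Lipg and Dgat2 were among the 12 largest increases. Lipg, which encodes endothelial lipase (chromosome 18, 74939322 to 74961263), rose from 6.97 ± 8.998 to 763 ± 68.9 normalised reads (log2 fold change 7.43 ± 0.93 SE, adjusted p = 0.00202). Its WT values were 0, 17.1 and 3.78, and the log2 fold change was 6.35 without WT replicate 1 and 8.44 without WT replicate 2. Dgat2, the enzyme of the last step of triglyceride synthesis (chromosome 7, 99153658 to 99182719), rose from 703 ± 131 to 6751 ± 1200 (3.26 ± 0.18, adjusted p = 0.000333). Degs2, a sphingolipid desaturase and hydroxylase, rose by 3.79 on the log2 scale. The secreted granulocyte proteins Lrg1 and Lcn2 rose by 3.17 and 2.76, and the decoy receptor Il1r2 by 3.21, or 3.94 without KO replicate 2. Smoc2 (6.37), Tmem170b (3.47), Olfml2b (2.71), Kcnj2 (2.66) and Ccno (2.63) also belonged to the group, and Olfml2b lost its call without WT replicate 1. Smoc2 stood at 5.44 without WT replicate 2 and at 6.99 without WT replicate 3. The 12 largest decreases were all immunoglobulin variable genes. Igkv8-30 averaged 836 ± 220 in WT and 0 in every KO library, at least 279-fold lower against a floor of 3 reads per library. Igkv6-23, Igkv14-126, Ighv1-9, Ighv11-2, Ighv1-26, Igkv4-61, Igkv6-15, Ighv5-16, Igkv10-96 and Igkv8-21 were likewise at 0 in KO. Their WT means lay between 252 and 649 and varied widely between WT libraries, as in Igkv8-21 with 533, 878 and 15.1. Ighv1-55 averaged 354 in WT and 1.79 in KO, where KO replicate 1 had 5.36 and KO replicates 2 and 3 had 0. Its log2 fold change was −7.56, or −8.45 without KO replicate 1. These genes belong to families of near-identical members, so the reads of any single one are uncertain.

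Stem cell genes fell in KO, in libraries whose share of stem cells was not determined. Of 48 tested stem cell genes, 38 fell and 2 rose (42 and 2 adjusted over the list alone), with a median log2 fold change of −1.79. The list passed camera with a preset correlation (adjusted p = 1.65e-16) and not with an estimated one (adjusted p = 0.18 with an estimated correlation). Mycn, a transcription factor, fell from 2621 ± 444 to 315 ± 92.0 normalised reads (log2 fold change −3.07 ± 0.22 SE, adjusted p = 0.000429). The transcription factors Gfi1b (−2.30), Mecom (−2.23) and Hlf (−1.30) fell, as did the surface markers Slamf1 (−2.39), Procr (−2.22) and Cd34 (−1.32). Flt3, a cytokine receptor of multipotent progenitors, fell to 33.4% of its WT level (−1.59), and Trim47 to 19.6% (−2.34). Kit, the stem cell factor receptor, fell to 63.4% (−0.65, adjusted p = 0.0119), a call that was lost without the intensity trend (adjusted p = 0.0655). Ly6a, which encodes the marker Sca-1, averaged 613 ± 257 in WT and 480 ± 108 in KO and did not pass (−0.29, adjusted p = 0.555), and without WT replicate 2 its sign turned. The members that rose, named here after their values were seen, were Fli1 (0.40) and Ifitm1 (0.76).

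Granulocyte-monocyte progenitor genes rose. Of 28 tested, 19 rose and 3 fell (21 and 3 adjusted over the list alone), with a median of 0.54 (camera adjusted p = 3.12e-08, and adjusted p = 0.202 with an estimated correlation). Ctsg, a protease of primary granules, rose from 106850 ± 13450 to 279820 ± 21310 (log2 fold change 1.39 ± 0.11 SE, adjusted p = 0.000595). Csf2rb, the shared beta chain of the GM-CSF, IL-3 and IL-5 receptors, rose by 1.62 on the log2 scale, and Ms4a3, a marker of these progenitors, rose to 284% of its WT level. Mpo, the granule gene with 2.0% to 2.23% of all reads in WT, held 2.28% to 2.57% in KO. Irf8 (−1.05) and Ly86 (−0.88), named after their values were seen, fell together with Flt3.

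Among mature granulocyte genes, 11 of 24 rose, 2 fell and 11 did not pass the test (14 rose and 2 fell adjusted over the list alone), with a median of 0.97 (camera adjusted p = 0.000252, and adjusted p = 0.39 with an estimated correlation). Wfdc21 rose to 403% of its WT level, and Trem1, a receptor that amplifies inflammation (log2 fold change 1.25), and Lcn2 rose as well. Retnlg, a secreted product of mature neutrophils, fell to 27.3% of its WT level (−1.87), and Padi4, named after its value was seen, fell by 1.21 on the log2 scale. Monocyte and macrophage genes went the other way: 12 of 28 fell and 1 rose (16 and 3 adjusted over the list alone), with a median of −1.56 (camera adjusted p = 0.00109, and adjusted p = 0.51 with an estimated correlation). The lysozyme gene Lyz2 (−1.32), the haptoglobin-hemoglobin scavenger receptor Cd163 (−2.58) and Adgre1, which encodes F4/80 (−1.99), fell, and the endotoxin co-receptor Cd14 rose (1.32). Neither of these lists passed fry's directional test (adjusted p = 0.0668 and 0.0801).

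**Figure D2:**
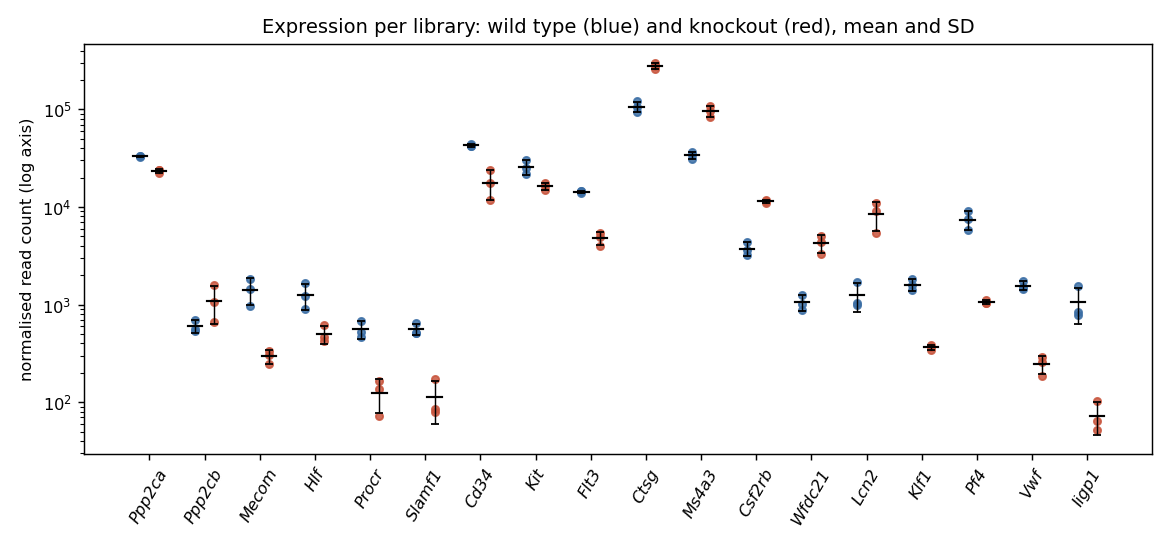
Normalised read counts on a log axis for 18 named genes, with WT libraries in blue, KO libraries in red and bars for mean and SD (n = 3). Ctsg, Ms4a3, Csf2rb, Wfdc21 and Lcn2 lie higher in KO, most stem cell, erythroid and megakaryocyte genes lie lower, and Ppp2ca keeps 70.5% of its WT level.

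Erythroid and megakaryocyte genes fell. Of 35 erythroid genes, 23 fell and 2 rose (25 and 2 adjusted over the list alone), with a median of −1.65 (camera adjusted p = 1.48e-09, and adjusted p = 0.112 with an estimated correlation). Klf1, the erythroid master transcription factor, fell to 22.7% of its WT level (−2.13), the carbonic anhydrase Car2 to 19.8% (−2.32), the water channel Aqp1 to 19.1% (−2.37) and the biliverdin reductase Blvrb to 34.7% (−1.52). Tfrc, the transferrin receptor, and the mitochondrial iron importer Slc25a37, both named after their values were seen, rose by 1.44 and 0.41. Of 32 megakaryocyte and platelet genes, 21 fell and 1 rose (24 and 2 adjusted over the list alone), with a median of −1.98 (camera adjusted p = 5.55e-13, and adjusted p = 0.112 with an estimated correlation). The platelet chemokine Pf4 fell from 7443 ± 1665 to 1064 ± 53.9 (−2.78 ± 0.16 SE, adjusted p = 0.000390). Vwf, the von Willebrand factor (−2.69), Rab27b (−2.89) and the guanylate cyclase subunit Gucy1a3 (−3.20) fell as well. Of 19 mast cell, basophil and eosinophil genes, 14 fell and 0 rose (16 and 0 adjusted over the list alone), with a median of −1.87 (camera adjusted p = 4.82e-08, and adjusted p = 0.276 with an estimated correlation). They included the basophil protease Prss34 (−2.56), the eosinophil granule gene Prg3 (−2.76), the mast cell carboxypeptidase Cpa3 (−0.96) and Slc45a3 (−1.95).

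Lymphoid and dendritic cell genes fell, and 0 of their tested members rose when adjusted over all genes. Of 22 B lineage genes, 13 fell (15 adjusted over the list alone), with a median of −2.69 (camera adjusted p = 1.17e-07, and adjusted p = 0.18 with an estimated correlation). Igkc, the kappa constant region, fell from 17627 ± 10380 to 510 ± 263 (−5.11 ± 0.50 SE, adjusted p = 0.000887). The antigen presentation genes H2-Ab1 (−1.62), H2-Aa (−3.18) and Cd74 (−3.13) fell. Of 24 T, NK and innate lymphoid genes, 12 fell (camera adjusted p = 1.34e-05, and adjusted p = 0.15 with an estimated correlation). Their median was −1.95, or −1.87 with a member that is at 0 in one group set to its bound. Adjusted over the list alone, 14 fell and 1 rose. The T cell receptor constant gene Trbc1 (−3.64), the transcription factor Gata3 (−2.79) and the IL-7 receptor gene Il7r (−3.03) fell, from WT means of 171, 626 and 180 normalised reads. Of 19 dendritic cell genes, 11 fell, also when adjusted over the list alone, with a median of −1.49 (camera adjusted p = 3.50e-06, and adjusted p = 0.112 with an estimated correlation). Tcf4, a transcription factor of plasmacytoid dendritic cells, fell to 57.4% of its WT level (−0.81). Of 15 stromal and endothelial genes, 6 fell and 2 rose (7 and 2 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.108) but passed fry's directional test (adjusted p = 0.00248). Emcn, an endothelial and stem cell sialomucin, fell by 4.18 on the log2 scale and the secreted phosphoprotein Spp1 rose by 1.42.

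Interferon response genes fell. Of 58 tested, 41 fell and 0 rose (44 and 0 adjusted over the list alone), with a median of −1.12 (camera adjusted p = 2.11e-15, and adjusted p = 0.18 with an estimated correlation). The GTPase Iigp1 fell from 1056 ± 427 to 72.8 ± 27.0 (−3.83 ± 0.36 SE, adjusted p = 0.000804). Usp18, which restrains interferon signalling (−3.08), the 2'-5'-oligoadenylate synthetase-like gene Oasl2 (−1.82) and Irf9, the DNA-binding part of the interferon-activated complex (−1.36), fell as well. The macrophage, dendritic, B lineage and T and NK lists fell alongside, with medians of −1.56, −1.49, −2.69 and −1.95. NF-kB and inflammatory genes went both ways: 8 of 38 fell and 4 rose (9 and 5 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.395). Il18 fell by 3.51 and Il1a by 3.13 on the log2 scale, the inhibitor Nfkbie fell by 0.75, and the NF-kB cofactor Bcl3 rose by 1.29.

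Genes of ribosome production and protein folding rose. Of 56 MYC target and ribosome biogenesis genes, 36 rose and 2 fell (44 and 2 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 1.16e-14, and adjusted p = 0.18 with an estimated correlation). The nucleolar genes Ncl (0.95), Noc4l (0.81) and Npm1 (0.67) rose. The members that fell were Mycn and Myc themselves. Myc fell to 72.0% of its WT level (−0.47, adjusted p = 0.0208), a call that was lost in 5 of 19 alternatives, among them without WT replicate 2, WT replicate 3, KO replicate 2 or KO replicate 3, with an adjusted p of up to 0.0946. Of 87 cytosolic ribosomal protein genes, 36 rose and 2 fell (45 and 3 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 6.32e-11, and adjusted p = 0.366 with an estimated correlation). Quantile normalization ended that call (adjusted p = 0.0528), with a median of 0.13. Rpl7a (0.63), Rpl10 (0.62), Rps10 (0.64) and Rpl30 (0.48) rose. These genes have many processed pseudogenes, so their counts are uncertain. Of 37 unfolded protein and integrated stress response genes, 24 rose and 2 fell (26 and 3 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 6.12e-11, and adjusted p = 0.18 with an estimated correlation). The chaperone cofactor Sdf2l1 rose from 10087 ± 507 to 25145 ± 1973 (1.32 ± 0.09 SE, adjusted p = 0.000429). The disulfide oxidase Ero1l (1.42), the mitochondrial one-carbon enzyme Mthfd2 (1.42) and the amino acid transporter Slc7a5 (0.90) rose. Trib3 (−1.30) and Ppp1r15a (−0.81), which act downstream of ATF4 and were named after their values were seen, fell.

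Among the energy metabolism genes that passed the test, more rose than fell. KO values summed to more than WT values on the scale used, so small rises here depend on the scaling. Of 33 glycolysis genes, 18 rose and 6 fell (19 and 9 adjusted over the list alone), with a median of 0.60 (camera adjusted p = 0.000851, and adjusted p = 0.18 with an estimated correlation). The glycolytic enzymes Gpi1 (0.99) and Pgk1 (0.80) rose, as did the lactate transporter Slc16a1, to 228.5% of its WT level. Pdk2, a kinase that holds pyruvate back from the mitochondria, fell to 25.1% of its WT level (−1.99). Of 83 nuclear oxidative phosphorylation genes, 24 rose and 1 fell (28 and 1 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 4.62e-07, and adjusted p = 0.465 with an estimated correlation). Cyc1 (0.71), Atp5g3 (0.67) and Cox5a (0.62) rose, and Atp5s, named after its value was seen, fell by 0.38 on the log2 scale. Of 37 oxidative stress and NRF2 genes, 12 rose and 5 fell (16 and 5 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.00119, and adjusted p = 0.276 with an estimated correlation). Ncf1, a subunit of the phagocyte NADPH oxidase (1.11), the pentose phosphate enzymes Pgd (0.99) and G6pdx (0.78) and the glutathione reductase Gsr (0.98) rose. The NRF2 targets Nqo1 (−1.06), Hmox1 (−1.57) and Srxn1 (−0.93), named after their values were seen, fell, as did Prdx2 and Cat. Quantile normalization ended the calls of the oxidative phosphorylation list (adjusted p = 0.147) and of the NRF2 list (adjusted p = 0.606), and the former also failed fry's directional test (adjusted p = 0.0714).

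**Figure D3:**
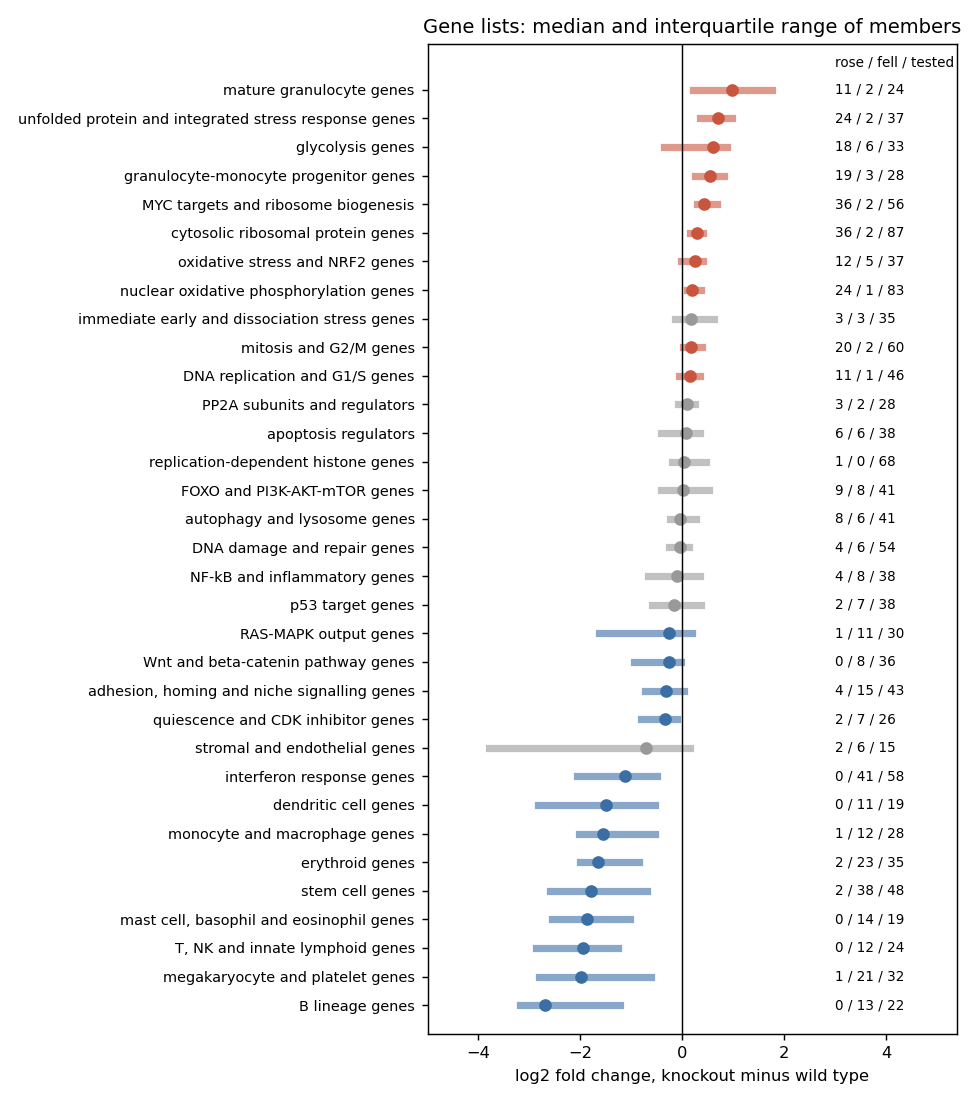
Median log2 fold change (points) and interquartile range (bars) of the tested members of each of 33 gene lists, KO minus WT, with the numbers that rose, fell and were tested at the right. Lists called up by camera with a preset correlation are red, called down blue and not called grey, and B lineage genes have the lowest median (−2.69) and mature granulocyte genes the highest (0.97). The G1/S list turns to a median of −0.04 and loses its call under quantile normalization.

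Most cell cycle genes did not pass the test, and the median changes of their lists were small. Those small medians depend on the scaling, since KO values summed to more than WT values. Of 60 mitosis and G2/M genes, 20 rose and 2 fell (23 and 3 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 4.29e-05, and adjusted p = 0.366 with an estimated correlation). Ccnb1, which encodes cyclin B1, rose from 12280 ± 440 to 18657 ± 1124 (0.60 ± 0.08 SE, adjusted p = 0.00237), and Cdca3 rose by 0.57. Of 46 DNA replication and G1/S genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.00480, and adjusted p = 0.357 with an estimated correlation). Rrm2, the small subunit of ribonucleotide reductase, rose to 230.1% of its WT level and the transcription factor E2f2 by 0.64 on the log2 scale. Quantile normalization ended both calls and turned the median of the G1/S list to −0.04. Of 26 quiescence and CDK inhibitor genes, 7 fell and 2 rose (8 and 2 adjusted over the list alone), with a median of −0.34 (camera adjusted p = 0.00446, and adjusted p = 0.334 with an estimated correlation). Cdkn1b, which encodes p27 (−0.81), Ccng2 (−1.12) and Ccnd1, a cyclin that promotes the cycle (−1.29), fell, while the transcriptional repressor Gfi1 rose (0.77). Of 68 replication-dependent histone genes, 1 rose, Hist1h3d (1.06), also when adjusted over the list alone, and 0 fell. That list did not pass camera (adjusted p = 0.41), but passed under quantile normalization (adjusted p = 0.0273). Poly(A) selection recovers most such transcripts poorly.

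Lists of p53 targets, apoptosis and DNA repair did not pass camera (adjusted p = 0.336, 0.471 and 0.471), while the p53 target list passed fry's directional test (adjusted p = 0.0176). Of 38 p53 target genes, 7 fell and 2 rose (7 and 3 adjusted over the list alone). Pmaip1, which encodes the pro-apoptotic protein NOXA, rose from 1275 ± 366 to 5412 ± 1206 (2.10 ± 0.24 SE, adjusted p = 0.00162), while Sesn1 (−1.64) and Plk2 (−2.50) fell. Trp53 itself averaged 18207 in WT and 14473 in KO (−0.34, adjusted p = 0.0879), which passed only with library quality weights, under quantile normalization and without KO replicate 2. Cdkn1a, which encodes p21, did not pass (−0.26, adjusted p = 0.313). Of 38 apoptosis regulators, 6 rose and 6 fell (7 and 6 adjusted over the list alone), among them Cycs up (0.59) and the caspases Casp6 (−1.10) and Casp2 (to 49.5% of its WT level) down. Of 54 DNA damage and repair genes, 4 rose and 6 fell, also when adjusted over the list alone, with decreases in Xrcc5 (−0.53) and Trp53bp1 (−0.67).

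RAS-MAPK output genes fell in part. Of 30 tested, 11 fell and 1 rose, also when adjusted over the list alone, with a median of −0.25 (camera adjusted p = 0.0224, and adjusted p = 0.18 with an estimated correlation). The MAP kinase phosphatases Dusp5 (−2.32) and Dusp6 (−1.75) and the transcription factor Etv5 (−1.84) fell. Of 43 adhesion, homing and niche signalling genes, 15 fell and 4 rose (16 and 5 adjusted over the list alone), with a median of −0.32 (camera adjusted p = 0.0136, and adjusted p = 0.51 with an estimated correlation). The guidance receptor Robo4 (−3.75) and the adhesion molecule Esam (−2.57), both also in the stem cell list, fell. Without WT replicate 2 the RAS-MAPK and adhesion lists lost their calls (adjusted p = 0.0514 and 0.0506), and the adhesion list also failed fry's directional test (adjusted p = 0.0668). Of 36 Wnt and beta-catenin pathway genes, 8 fell and 0 rose, also when adjusted over the list alone, with a median of −0.26 (camera adjusted p = 0.0188, and adjusted p = 0.276 with an estimated correlation). Fzd8 (−3.90, or −3.14 without KO replicate 3) and Tcf7l2 (−2.28) fell. That call was lost with a minimum value of 10 (adjusted p = 0.0693) and in edgeR (adjusted p = 0.124). Ctnnb1, which encodes beta-catenin, did not pass (0.13, adjusted p = 0.792), and its sign turned without WT replicate 2, without KO replicate 1, with library quality weights and under quantile normalization.

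The remaining lists had members in both directions and did not pass camera. Of 41 FOXO and PI3K-AKT-mTOR genes, 9 rose and 8 fell (11 and 10 adjusted over the list alone, camera adjusted p = 0.829), and the median (0.02) and the mean (−0.06) differed in sign. Trib2 (−3.40) and the ubiquitin ligase gene Fbxo32 (−2.25) fell and the kinase subunit Pik3cb rose (1.05). Of 41 autophagy and lysosome genes, 8 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.518), with a median of −0.04 although camera's direction was up. The alpha-galactosidase gene Gla (0.92) and Lamp2 (0.60) rose and the cathepsin gene Ctss fell (−0.64). Of 35 immediate early and dissociation stress genes, 3 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.296, or 0.0286 without KO replicate 1). Gadd45b rose (1.46) and the nuclear receptor gene Nr4a1 fell (−2.91). Xist fell to 50.6% of its WT level (−0.94, adjusted p = 0.0179) and its antisense partner Tsix to 51.1% (−0.97), and without stated strand the reads of this pair cannot be separated. The Xist call was lost without the intensity trend and without WT replicate 1, KO replicate 1 or KO replicate 3. In all, camera with a preset correlation called 23 of 33 lists, 10 up and 13 down, and none with an estimated correlation, where the smallest adjusted p was 0.112 and 7 lists had an unadjusted p below 0.05. Fry's directional test called 21 lists.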

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

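Alternatives with edgeR, DESeq2, TMM scaling or a minimum of 10 were chosen after seeing the data, and the others before. Under every alternative except the 2-fold minimum, which it does not reach, Ppp2ca was lower in KO and passed the test, with a log2 fold change between −0.78 and −0.46 and an adjusted p of at most 0.0365. In no alternative was a called gene called in the opposite direction. The count of higher genes was 1071 without the intensity trend and 3198 with library quality weights, against 2069. A 2-fold minimum left 493 higher and 1671 lower genes, by its own construction. Leaving out one library gave 978 to 1808 higher and 1617 to 2548 lower genes, with fewer samples in each fit. EdgeR on the recovered reads called 2075 higher and 2496 lower, with 4314 of the 4691 called genes among them, and DESeq2 2424 and 2960, with 4510 among them. Quantile normalization moved the median log2 fold change of all genes from −0.023 to 0.077 and called 19 lists. Camera with an estimated correlation called 0 of the 23 lists. Under quantile normalization the median of the G1/S list (−0.039) and the value of Ctnnb1 (−0.040) turned negative. Camera's direction turned there for the autophagy (median −0.083), FOXO (0.035) and immediate early (0.043) lists. Ctnnb1 was −0.22 with quality weights and −0.11 to 0.43 with one library left out, Ly6a −0.57 to 0.021 and the immediate early list −0.10 to 0.37. Camera's direction also turned for the FOXO list in edgeR (0.014). The cause of these changes was not tested. Of the named genes' values over all alternatives, 2970 kept direction and side of the threshold, 34 lost the call, 10 gained it and 5 reversed. Of the list values, 615 kept both, 35 lost the call, 4 gained it and 6 reversed. The labels do not state whether equal replicate numbers are pairs. Correlations of same-numbered deviations from the group means were −0.023, −0.011 and −0.021. No shared replicate effect showed, which does not exclude a pairing. With the replicate block 1705 genes were higher and 2157 lower, 23 lists were called and Ppp2ca had an adjusted p of 0.0112, while Ppp2cb passed and C330027C09Rik did not. TPM values were not used. Median-of-ratios scaling of the deposited values was not run, since their factor was 1.0074 in each of the 6 libraries. DESeq2 gave no list test. In simulations most 1.5-fold changes were missed, but few genes were changed there, so that share does not carry over to the real comparison. A gene without a call may still differ.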

Other observations

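Several gene groups outside the fixed lists were put together and tested after the values were seen, and members of all of them were named on the same basis. Of 28 cholesterol and fatty acid synthesis genes, 15 rose and 0 fell (median log2 fold change 0.58, camera adjusted p = 1.34e-08, and adjusted p = 0.146 with an estimated correlation). Fdps, an enzyme of isoprenoid synthesis, rose by 1.45 and Fasn, the fatty acid synthase, by 1.29. Of 20 cytosolic aminoacyl-tRNA synthetase genes, 14 rose and 0 fell (median 0.45, camera adjusted p = 2.37e-10, and adjusted p = 0.0865 with an estimated correlation), Aars by 0.85. Of 38 proteasome subunit genes, 23 rose and 2 fell (median 0.41, camera adjusted p = 4.13e-10, and adjusted p = 0.146 with an estimated correlation). Psmb5, a catalytic subunit, rose by 0.68, while Psmb9, a subunit of the immunoproteasome that also stands in the interferon list, fell by 0.52 on the log2 scale, and Psma8 fell by 1.57.

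All 8 tested Gimap genes, GTPases of lymphocytes, fell (median −3.28, camera adjusted p = 1.28e-06, and adjusted p = 0.0749 with an estimated correlation), and Gimap6 fell from 7243 ± 1420 to 495 ± 225. Of 22 MHC genes, 16 fell and 0 rose (median −0.93, camera adjusted p = 2.37e-10, and adjusted p = 0.0749 with an estimated correlation), some of which the B lineage list also holds. Of 14 Hox genes, 6 fell and 0 rose (median −1.74, camera adjusted p = 2.45e-04, and adjusted p = 0.0614 with an estimated correlation), among them Hoxa9 (−1.04) and Hoxb5 (−3.96), which are also stem cell list members. Of 64 immunoglobulin genes, 40 fell and 0 rose (camera adjusted p = 2.23e-14, and adjusted p = 0.0614 with an estimated correlation). Their median was −4.80, or −4.61 with the 25 members that are at 0 in a group set to their bound. Those members passed the filter only through the other group, which fixes their direction. Of 382 listed genes only the 64 were tested, so the test restates the largest falls.

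In the tests below, those on depth, on GC content and length and on the kappa variable genes were set before their results were seen, and the others after. The stem cell, erythroid, megakaryocyte, mast cell and basophil, lymphoid, dendritic and macrophage lists had medians below 0 in KO, and the granulocyte lists above 0. Not all members passed, and none of these lists passed camera with an estimated correlation. The macrophage and mature granulocyte lists also failed fry's directional test (adjusted p = 0.0801 and 0.0668). These medians changed little at equal depth and after removal of a trend on GC content and length. Thinned values were scaled back, so thinning could move mainly genes with few reads. The log2 fold change had Spearman correlations of 0.028 with GC content and −0.049 with length, so there was little trend to remove. With every library thinned to the smallest total, 37951985 reads, 4629 genes were called and the stem cell median was −1.85. After removal of the trend on GC content and length it was −1.75. The medians of the 7 other lower lists stayed between −2.60 and −1.52 after thinning and between −2.70 and −1.51 after the correction, and those of the progenitor and mature granulocyte lists were 0.54 and 0.98, and 0.58 and 0.99. A carry-over of mature blood cells into the WT libraries stays open: the mature granulocyte median was 0.97, but that rise is part of the pattern itself, and Retnlg (−1.87) and Padi4 (−1.21) fell. A different mix of stages in the sorted cells may also account for the pattern, a hypothesis that the medians of 8 of 8 lists of other lineages, from −2.69 to −1.49, only restate and bulk values cannot separate from a change within cells, nor can the log2 ratio of Ctsg to Mpo, which was 1.02 higher in KO (−3.17 ± 0.07 in WT and −2.15 ± 0.07 in KO, SD, n = 3), because earlier progenitors make Mpo too.

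Immunoglobulin transcripts were far lower in KO than in WT but still present. Igkc had 25269, 11164 and 13423 reads in WT replicates 1 to 3 and 703, 236 and 632 in KO replicates 1 to 3. Kappa variable genes held 15217, 6710 and 7501 reads in the 3 WT libraries, from 61, 39 and 37 genes, and 377, 158 and 346 reads in the KO libraries, from 7, 5 and 11 genes. A very small number of antibody-secreting cells in WT would leave 1 variable gene dominant. The leading gene took 9.1%, 15.8% and 16.4% of the kappa variable reads in WT replicates 1 to 3 (the lowest being 9.1%). It was a different gene in each WT library. In KO replicates 1 to 3 the leading gene took 50.1%, 42.4% and 36.4%, and it was the same gene in KO replicates 1 and 3. The WT shares argue only against very few such cells in WT, since a larger number of antibody-secreting cells would give them too. The higher KO shares, from 377, 158 and 346 reads, leave very few such cells in KO open. Reads of near-identical family members are uncertain, and Jchain, a gene of antibody-secreting cells, differed widely among WT libraries, with 11030, 1218 and 5430 reads. A carry-over of many B lineage cells in WT, antibody-secreting cells included, a loss of such cells in KO mice and expression in progenitors stay open. The labels list no gate that would remove B lineage cells.

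In normalised reads Ppp2ca kept 70.5% of its WT level in KO, a share that depends on the scaling. Ppp2cb stood at 4.68% of the Ppp2ca level in KO, but reads of this paralog counted as Ppp2ca would lower its own count, so this stays open. Undeleted cells with wild-type expression stay open too: 1662 genes were called lower with KO means under 50% of WT, which a different mix of cells would also give. A candidate explanation is that transcripts of the recombined allele without the deleted exons are still counted over the rest of the gene, and the 70.5% cannot be told apart from a partial loss of whole transcripts without values per exon.

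The 6 libraries make 10 splits of 3 against 3, too few for a share below 0.05. The real split called 4691 genes and the highest other split 3 genes. For lists, the real split called 23 and 2 of the 10 splits gave as many: the highest other, WT replicates 1 and 2 with KO replicate 2, also called 23. Every other split has both genotypes on each side, so the genotype difference enters its within-side spread and few gene calls follow by construction. Part of that difference also remains between its sides, so its list calls, from 5 to 23, do not measure chance. Neither count thus tests the grouping.

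Immediate early and heat shock genes varied within both groups. Fos had 169410, 153210 and 32571 normalised reads in WT replicates 1 to 3 and 73087, 98645 and 90364 in KO replicates 1 to 3, and Egr1 had 35813, 27441 and 10249 in WT and 6947, 15366 and 11690 in KO. Hspa1a had 1375.5, 5655 and 249.8 in WT and 841, 6810 and 4106 in KO.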
